A study of Mus musculus with 18 samples.

How the data were processed

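RNA was measured in 18 libraries from axoplasm of C57B6 mice, made with the SMART-Seq v4 kit, a low-input method that amplifies full-length cDNA by PCR. Per the labels, axoplasm came from dorsal roots or sciatic nerves of the same animals, 5 animals were pooled for each biological repeat, and 3 independent biological repeats were made. Per the labels, about 200 ug of lysate was incubated for 3 h with 10 ug of a rabbit antibody to Kif5A or of rabbit IgG, the isotype control, and part of the lysate was sequenced as input. The 6 groups are thus Kif5A precipitate, IgG precipitate and input of each tissue, with 3 libraries in each. The titles number the libraries of every group from 1 to 3, but the labels do not state that libraries with equal numbers share their animals, so the numbers were not used to pair libraries in the reported fits.

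The deposited tables, 1 for each tissue, hold raw read counts for each Ensembl transcript, whole numbers that sum to between 11584418 and 22580824 per library. Per the submitters' processing notes, CASAVA 1.8.2, edgeR and the mouse genome build mm10 (GRCm38) were used. The aligner, the counting tool, whether counting used the strand and the annotation release are not given in the sources used here. The authors' tables also hold a normalized count per library, a signal scaled to a common library size, which was not used here. Per the file headers, the authors' log2 fold changes, p-values and false discovery rates for Kif5A against IgG and against input stand in the same tables; a few are quoted below as the authors' values. The 2 tables list different transcripts, and the smallest sum over the 9 libraries was 17 in both; whether a filter was applied is not given in the sources used here. The dorsal root table held 21207 transcripts and that of sciatic nerve 19096. Rows with no gene name, 283 and 266 of these, held between 0.138% and 0.237% of the counts of a library and were left out of library sizes and tests. No transcript of the mitochondrial chromosome stood in either table.

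Counts of the transcripts of each gene name were added up. Because the transcripts listed differ between the tissues, every fit used the 16878 named transcripts present in both tables, which gave 12697 genes, and the library size was the total of the named rows of the tissue's own table. A gene with further transcripts in its own tissue's table has counts that these sums leave out, so the sums over all transcripts were checked for the genes named in the Kif5A against IgG comparisons. Chromosome positions are those of the gene in GENCODE M21, on GRCm38. All 164 named genes were found there. Because the counting was not stated to use strand, reads of overlapping and antisense genes cannot be told apart. Globin, tubulin, ribosomal protein and mast cell protease genes have near copies, and their single values are uncertain to that extent.

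Groups were compared in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust fit, group means, TMM scaling, default filter on low counts by group). All p-values are two-sided and were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. The 12 precipitates were fitted together for Kif5A against IgG, for the difference of that ratio between tissues and for Kif5A precipitates of the 2 tissues. All 18 libraries were fitted together for the comparisons with input, and the 6 inputs alone for input against input. Standard errors (SE) of log2 fold changes come from this test. Levels, written CPM, are counts of named rows relative to the library size and the TMM factors, as mean ± SD of 3 libraries. Summed levels of gene lists are relative to the library size alone, without the TMM factors. Genes at 0 in all 3 libraries of a group have no finite ratio, so a lower bound against 3 counts over the group is given. With 1 to 3 counts, the ratio of the summed counts is given with its exact 95% Poisson interval. Such bounds and intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

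Before the data were examined, the following were set: the groups, the fits above, 24 lists of genes (cell types of nerve and its surroundings, parts of the axon, organelles and complexes) and the rule for named genes. For Kif5A against IgG in each tissue the rule takes 8 genes always (the Kif5 heavy chains, kinesin light chains and the mRNAs of Ncl, Kpnb1 and Mtor; 7 were measured). It adds up to 10 higher and 6 lower genes with the largest fold change past the threshold, with at least 10 CPM in the higher group and no overlap between replicates, topped up to 10 by the smallest p, and 3 members of each list with an adjusted p under 0.05. Other comparisons take 5 higher and 5 lower genes and the list members. Predicted genes were counted, not named. Lists were tested with camera of limma 3.58.1 at the preset correlation between genes of 0.01, which asks whether the genes of a list moved differently from other genes, with p adjusted over the 23 lists with a measured member. Camera was run again with an estimated correlation, along with fry, which asks only whether a list's genes move on balance in a direction. Of 58 list results past the threshold, 10 kept it with an estimated correlation and 26 with fry. Where only the preset call is past the threshold, the estimated value stands beside it.

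Alternatives set in the same way were DESeq2 1.42.0, its size factors in edgeR, library size alone, limma-voom, no filter and a stricter filter, all 18 libraries or only the compared groups, the replicate number as a block, other thresholds, library sizes without haemoglobin genes and leaving out each library. Alternatives chosen after the data were seen were edgeR's likelihood ratio test on genes and on transcripts, the quasi-likelihood test on transcripts, all transcripts of each own table, only genes above 0 in every IgG library, and, for comparisons of groups, leaving out a numbered replicate of every group. Where they moved a count of genes, their effects are given in the closing section. Relative to the TMM scaling, library size alone moved the median of all genes by 0.33 (log2) for Kif5A vs input in dorsal root, 0.18 for Kif5A vs input in sciatic nerve, 0.24 for IgG vs input in dorsal root and -0.11 for Kif5A in sciatic nerve against dorsal root, and DESeq2's size factors moved no median by over 0.04. Relative to the median of all genes, none of the 58 list results changed its sign with either scaling.

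The fits were tested on simulated data with the real library sizes, the common mean of the groups compared and the same spread for each gene in every group. Real IgG libraries spread more than Kif5A libraries, so the shares found in real data may differ. In the simulated data, 50 genes each were changed by 2, 4, 8 and 16 times. For Kif5A vs IgG in dorsal root, 0%, 12%, 28% and 50% of these were found, and in sciatic nerve 0%, 14%, 34% and 46%. For the difference between tissues 0%, 0%, 18% and 34% were found, and for the inputs 4%, 66%, 72% and 100%. The common biological coefficient of variation was 0.783 in the 12 precipitates, 0.678 in all 18 libraries and 0.403 in the 6 inputs. Replicate libraries were compared with each other, and no pair was alike within counting noise. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the figures.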

Results

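Kif5A is a heavy chain of the neuronal kinesin-1 motor, which carries cargo along microtubules away from the cell body. RNA that came down with a Kif5A antibody from mouse axoplasm was sequenced beside RNA that came down with an isotype control and RNA of the axoplasm itself, at 2 places. These were the dorsal root, close to the cell body, and the sciatic nerve, farther out. Each of the 6 groups held 3 libraries from independent biological repeats of 5 pooled animals. Total counts of dorsal root were 13443747, 11584418 and 18314126 in the IgG libraries, 15385098, 14731865 and 18705668 in the Kif5A libraries and 20022870, 18128453 and 16270677 in the inputs. Those of sciatic nerve were 21774833, 21323159 and 22580824 with IgG, 14658466, 19897848 and 17297357 with Kif5A and 16900707, 12256188 and 20249552 in the inputs.

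Genes with no count at all set the IgG libraries apart. Of the 12697 genes with a transcript in both tables, 9.18%, 8.02% and 5.65% had a count of 0 in the IgG libraries of dorsal root and 8.88%, 8.22% and 6.73% in those of sciatic nerve. The Kif5A libraries lay between 0.685% and 2.01% and the inputs between 0.362% and 1.06%. The IgG libraries of sciatic nerve had the most reads of all groups. Many genes higher with Kif5A than with IgG had such zeros. Among genes higher with Kif5A at an unadjusted p under 0.05, 56.5% in dorsal root and 55.0% in sciatic nerve had a 0 in at least 1 IgG library, against 15.1% and 15.3% of all genes tested. Among genes lower with Kif5A, 2.42% and 3.87% had a 0 in at least 1 Kif5A library. Genes with a 0 in IgG enter the first set more easily, so the shares only describe these genes.

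**Figure D1:**
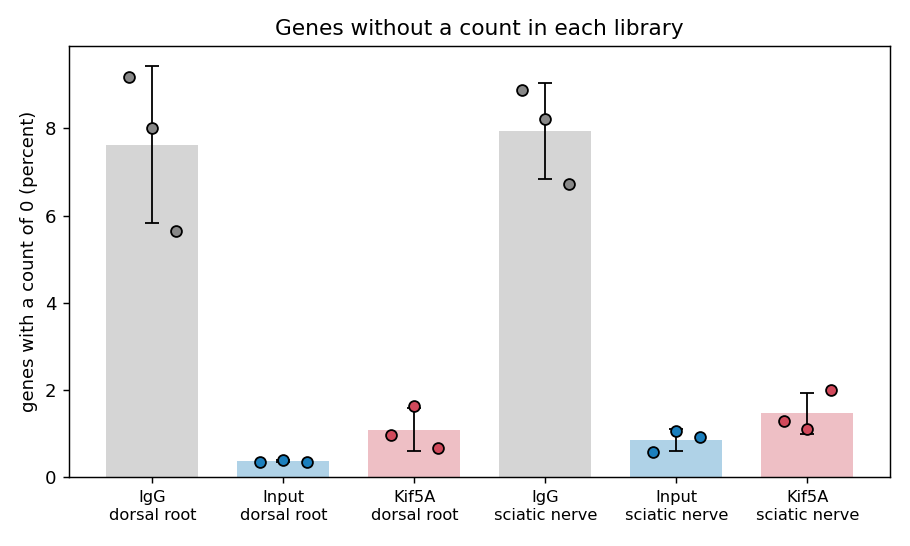
Percent of the 12697 genes with a count of 0 in each library (points), with the mean (bars) and SD (whiskers) of the 3 libraries of each group. IgG libraries lie between 5.65% and 9.18%, and no other library exceeds 2.01%.

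The comparison of Kif5A with IgG in dorsal root asks which mRNAs came down with the Kif5A antibody near the cell body. The mRNA of Kif5a itself (chromosome 10, 127225696 to 127263348) stood at 133 ± 37.6 CPM with the Kif5A antibody and 75.3 ± 59.96 CPM with IgG (SD, n = 3), a log2 ratio of 0.86 (SE 0.64). Kif5b, the widely expressed paralog (chromosome 18, 6201002 to 6242174), had 663 ± 101 and 689 ± 132 CPM, and Kif5c, the other neuronal paralog, had 124 ± 55.2 and 87.8 ± 48.1 CPM. Klc1, a kinesin light chain, had 24.0 ± 5.03 and 24.5 ± 21.9 CPM. Kpnb1, which encodes importin beta (chromosome 11, 97159714 to 97187881), had 231 ± 21.7 and 251 ± 60.3 CPM. Mtor, a growth-controlling kinase, had 38.8 ± 12.8 and 33.6 ± 14.3 CPM. Ncl, which encodes the RNA-binding protein nucleolin (chromosome 1, 86344719 to 86359400), had 381 ± 45.4 and 725 ± 307 CPM, with an adjusted p of 0.611. None of these passed the test, and the directions of Kif5b, Klc1 and Kpnb1 turned when single libraries were left out.

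None of the genes with the smallest p in dorsal root passed the threshold, and most had few or no IgG counts. Pcdhb16, a cell adhesion protein of the protocadherin beta cluster (chromosome 18, 37477814 to 37483038), had 6.89 ± 1.53 CPM with Kif5A and no count with IgG, at least 104-fold higher. The synaptotagmin relative Syt15 was at least 24.0-fold higher and Tldc2 at least 23.6-fold higher, both also without an IgG count. Dab2ip, a Ras GTPase activator that limits growth signalling (chromosome 2, 35558266 to 35730994), had 4.83 ± 1.35 CPM and no IgG count over the transcripts shared by both tables. Over all Dab2ip transcripts of the dorsal root table, however, IgG held 37 counts and Kif5A 297, against 0 and 268 over the shared transcripts. Cand2, a regulator of ubiquitin ligases (chromosome 6, 115774538 to 115805557), had 20.0 ± 2.74 and 0.817 ± 0.457 CPM, a log2 ratio of 4.66 (SE 0.78, adjusted p = 0.144). Enc1, an actin-binding protein of neurons, had 17.97 ± 12.7 and 0.0830 ± 0.0863 CPM, and Clic6, a chloride channel family member, had a log2 ratio of 2.53 with an adjusted p of 0.176. St6galnac5, a sialyltransferase, and Myct1 had log2 ratios of 5.68 and 5.22. Bik, a promoter of apoptosis, had a single IgG count, and its ratio was 90.0 with an interval of 15.8 to 3588.

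In edgeR's quasi-likelihood test, 0 of 12551 genes passed in dorsal root, with a smallest adjusted p of 0.105; 543 genes were higher and 207 lower at an unadjusted p under 0.05. DESeq2 called 158 genes for Kif5A vs IgG in dorsal root, and leaving out IgG replicate 3 gave 2 with edgeR. Genes whose replicates did not overlap between the groups made up 13.3%, where chance gives 10%. No list had an adjusted p under 0.05. Of 34 RNA granule proteins 7 had a positive log2 ratio, with a median of -0.22 (camera adjusted p = 0.061). Of 13 genes of sensory neurons 10 were positive, with a median of 0.57 (adjusted p = 0.313), and 1 was higher when adjusted over the list alone.

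The same comparison in sciatic nerve asks which mRNAs came down with the Kif5A antibody farther out. It cannot place an mRNA in the axon or on the motor. Genes of adipocytes, fibroblasts and myelinating Schwann cells summed to 43804 ± 34741, 19282 ± 2347 and 18775 ± 13195 CPM with Kif5A there. Mmp9, a secreted protease that cuts extracellular matrix (chromosome 2, 164940780 to 164955850), had 17.7 ± 8.79 CPM with Kif5A and 0.209 ± 0.200 CPM with IgG (SD, n = 3), an 85.8-fold difference (log2 6.42, SE 0.78, adjusted p = 0.0114). Brf2, a subunit of RNA polymerase III initiation factor (chromosome 8, 27123364 to 27128680), had 16.8 ± 3.02 and 0.0779 ± 0.0505 CPM, 202-fold (adjusted p = 0.0114). Fars2, the mitochondrial phenylalanine tRNA synthetase (chromosome 13, 36117412 to 36726280), had 15.03 ± 10.5 CPM with Kif5A and a single IgG count, and its ratio of 928 had an interval from 166 to 3.67e+04 (adjusted p = 0.0172). Clec2l, a lectin-like membrane protein of neurons (chromosome 6, 38663069 to 38680864), had 4.24 ± 1.55 and 0.0628 ± 0.0243 CPM, 62.2-fold. Chga, the chromogranin of dense-core vesicles (chromosome 12, 102554969 to 102565028), had 1.72 ± 0.503 CPM and a single IgG count, with a ratio of 109 and an interval from 19.2 to 4368 (adjusted p = 0.0359 for Clec2l and Chga). The sixth, the unannotated transcript 1700007L15Rik, lies outside the naming rule and was chosen after its values were seen; it had 19.7 ± 12.9 and 0.0933 ± 0.0768 CPM (adjusted p = 0.0114). In all 6, the 3 Kif5A libraries lay above the 3 IgG libraries.

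Kif5a mRNA had 29.8 ± 22.2 CPM with Kif5A and 5.91 ± 0.986 CPM with IgG in sciatic nerve, 5.21-fold, with all 3 libraries above all 3 (log2 2.38, SE 0.67), and did not pass (adjusted p = 0.239). The authors' deposited table gives its transcript a log2 fold change of 2.12 with a false discovery rate of 0.0556 there. Kif5b had 527 ± 39.6 and 478 ± 69.4 CPM, Kif5c 89.7 ± 20.7 and 59.3 ± 13.7 CPM, and Klc1 11.2 ± 1.21 and 14.9 ± 13.5 CPM, whose direction turned without IgG replicate 1. Kpnb1 had 281 ± 14.9 and 222 ± 38.1 CPM (log2 0.38, adjusted p = 0.804). Ncl had 427 ± 68.3 and 535 ± 62.6 CPM, and Mtor (chromosome 4, 148448611 to 148557683) had 45.0 ± 8.25 and 92.3 ± 54.7 CPM (log2 -0.98, adjusted p = 0.656). Just short of the threshold lay Ctu1, a tRNA thiolase, at 28.7 ± 5.15 and 2.43 ± 1.57 CPM (log2 3.59, adjusted p = 0.0566), and Sh3bgrl2, with 4.86 ± 2.32 CPM and no IgG count, at least 102-fold higher. Rab15, a GTPase of endosomes, Cog1, a part of the Golgi tethering complex, and Faim2, an inhibitor of neuronal apoptosis, had 3, 2 and 2 IgG counts. Their ratios were 250 (85.1 to 1215), 285 (78.4 to 2357) and 71.0 (19.2 to 593).

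**Figure D2:**
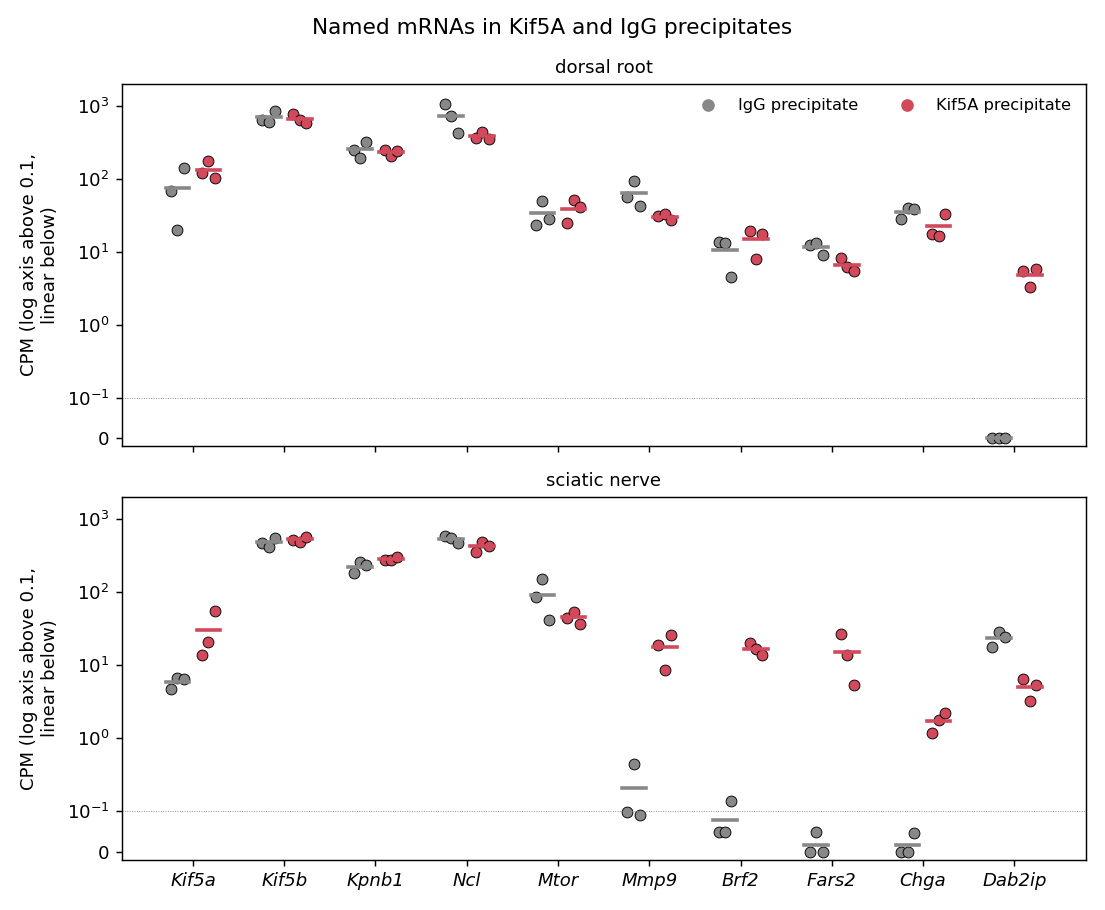
Levels of 10 mRNAs in CPM, on a log axis above 0.1 and linear below, in each IgG (grey) and Kif5A (red) precipitate of dorsal root (top) and sciatic nerve (bottom), over transcripts in both tables; lines are means of 3 libraries. Mmp9, Brf2, Fars2 and Chga lie below 0.5 CPM in the IgG libraries of sciatic nerve alone, and Dab2ip is at 0 in those of dorsal root.

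In all, 6 genes were higher and 0 lower for Kif5A vs IgG in sciatic nerve, with 776 higher and 284 lower at an unadjusted p under 0.05. DESeq2 called 411 and limma-voom 0. The replicate number as a block gave 1, and that block within each tissue 0. Adjusted p-values of the 5 rule genes ran up to 0.463 over their 15 alternatives. The count was 29 without IgG replicate 3, 1 without IgG replicate 2, 0 without Kif5A replicate 1, 2 without Kif5A replicate 2, 4 without Kif5A replicate 3 and 0 with any numbered replicate left out of every group. Non-overlapping genes made up 15.96%, against 10% by chance.

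Groups of mRNAs differed as well in sciatic nerve at the preset correlation. Lower with Kif5A than with IgG were all 9 adipocyte genes (median log2 -0.67, adjusted p = 2.1e-05; 0.793 with an estimated correlation), such as Fabp4, a fatty acid carrier, at 4717 ± 3087 against 14349.5 ± 4229.8 CPM. Their summed level overlapped between the groups, at 43804 ± 34741 CPM with Kif5A and 67701 ± 36609 CPM with IgG, and was lowest in replicate 3 of both (7496 and 30222 CPM). So were 50 of 61 respiratory chain genes (11 positive, median -0.36, adjusted p = 1.9e-04; 0.943 estimated), with Ndufa9 at 163 ± 10.6 and 317 ± 144 CPM and Ndufc2 at 154 ± 27.1 and 307 ± 52.9 CPM. Lower too were cytosolic ribosomal protein genes (26 of 79 positive, median -0.19, adjusted p = 0.00436; 0.943 estimated), with Rpl12 at 23.2 ± 1.74 and 54.6 ± 12.9 CPM. Genes of the axonal cytoskeleton lay higher (17 of 19 positive, median 0.34, adjusted p = 0.0258; 0.807 estimated). This lean was not particular to axonal genes: myelinating Schwann cell genes (17 of 21 positive, median 0.51, adjusted p = 0.273) and erythroid genes (6 of 7 positive, median 1.26, adjusted p = 0.131) leaned the same way without passing. Among the cytoskeleton genes were Tubb3, the neuronal beta-tubulin, at 3.94 ± 0.850 and 0.242 ± 0.381 CPM, Tuba1b at 1271 ± 343 and 809 ± 157 CPM, and Mapt, which encodes tau, at 57.1 ± 2.61 and 25.5 ± 16.4 CPM. Fibroblast genes (10 of 21 positive, median -0.28, adjusted p = 0.0258; 0.793 estimated) were led by Moxd1, higher at 34.7 ± 7.55 against 12.6 ± 10.5 CPM, and the collagen gene Col1a2, at 2640.3 ± 558 against 4053 ± 803 CPM. Nuclear-retained RNAs (3 of 8 positive, median -0.70, adjusted p = 0.0258; 0.793 estimated), with Snhg11 at 130 ± 94.2 against 499 ± 198 CPM, were lower by median. Their summed level, relative to library size alone, overlapped between the groups and showed no clear direction, at 34312 ± 23004 CPM with Kif5A and 30860 ± 13523 CPM with IgG. Lower as well were endothelial genes (5 of 16 positive, median -0.34, adjusted p = 0.036; 0.793 estimated), with Egfl7 at 22.9 ± 0.809 against 62.7 ± 7.03 CPM. No single member of the lists past the threshold passed, over all genes or adjusted over the list alone.

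Whether recovery with the Kif5A antibody differs between the 2 places was asked by the ratio of the ratios. For Mmp9 the Kif5A libraries lay above IgG in sciatic nerve, whereas in dorsal root they had 30.0 ± 2.81 CPM and IgG 63.2 ± 25.7 CPM (SD, n = 3), a difference of 7.44 on the log2 scale (SE 0.97, adjusted p = 0.0364). For Dab2ip it was the reverse: 4.98 ± 1.62 CPM with Kif5A and 23.5 ± 5.66 CPM with IgG in sciatic nerve, a difference of -11.68 (SE 1.41, adjusted p = 0.0364) over the transcripts in both tables. This fitted value rests on the IgG zeros of dorsal root; over all transcripts of each table Dab2ip gave -4.69 with an adjusted p of 0.534. Fars2 (10.15, adjusted p = 0.0526; 6.54 ± 1.40 and 11.4 ± 2.22 CPM in dorsal root) leaned as Mmp9 did. So did Brf2 (7.08, adjusted p = 0.0778; 14.8 ± 6.002 and 10.3 ± 5.08 CPM in dorsal root) and Chga (6.89, adjusted p = 0.0838; 22.2 ± 9.42 and 35.1 ± 6.14 CPM in dorsal root). Syt15, Myct1, St6galnac5 and Enc1, near 0 in IgG of dorsal root, leaned the other way, and Cog1 as Mmp9. In this comparison, Kif5A vs IgG difference between sciatic nerve and dorsal root, 1 gene was higher and 1 lower of 12551, 800 had an unadjusted p under 0.05, and DESeq2 called 188. Adjusted p-values ran from 1.34e-13 to 0.860 for Mmp9 and from 3.95e-11 to 0.801 for Dab2ip over 21 alternatives. The count was 0 when any Kif5A library, IgG replicate 1 of either tissue or dorsal root IgG replicate 2 was left out. It was 6 without dorsal root IgG replicate 3, 1 without sciatic nerve IgG replicate 2 and 24 without sciatic nerve IgG replicate 3. It was 0 over all transcripts of each table and with either replicate block. Of 61 respiratory chain genes 6 were positive, with a median of -0.55 (adjusted p = 0.00127; 0.959 estimated), and no other list differed between the tissues.

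Kif5A against input asks which mRNAs are over- or under-represented in the precipitate relative to the axoplasm. In dorsal root, mRNAs of ribosomal proteins and of the respiratory chain were lower as lists. Translation factors did not pass as a list (16 of 31 positive, median 0.041, camera adjusted p = 0.566). Their summed level was nonetheless lower with Kif5A, at 8825, 9679 and 10922 CPM against 12271 to 13158 CPM in input. Of 79 cytosolic ribosomal protein genes 3 were positive, with a median log2 ratio of -1.07 and 20 lower when adjusted over the list alone (adjusted p = 1.2e-29; 0.395 estimated). Rps24 had 65.3 ± 39.4 CPM with Kif5A and 249.5 ± 36.3 CPM in input (SD, n = 3), and Rpl23a 43.1 ± 15.4 and 118 ± 16.3 CPM. Of 61 respiratory chain genes 9 were positive, with a median of -0.97 and 7 lower over the list alone (adjusted p = 1.3e-18; 0.395 estimated). Uqcrb, of complex III, had 283 ± 163 and 1059 ± 310 CPM, Ndufb6 118 ± 85.4 and 407 ± 99.6 CPM and Ndufa5 72.9 ± 33.8 and 259 ± 108 CPM. Kif5A replicate 3 stood apart in both lists: the summed level of the ribosomal protein genes was 8582, 10181 and 20009 CPM with Kif5A, against 23087 to 25395 CPM in input, and that of the respiratory chain genes 7166, 8853 and 17475 CPM against 17834 to 19439 CPM. Skeletal muscle genes (1 of 12 positive, median -1.07, 1 lower over the list alone, adjusted p = 0.00662; 0.395 estimated), with the actin Acta1 at 18.5 ± 10.8 and 54.2 ± 17.3 CPM, were lower than other genes. So were erythroid genes (2 of 7 positive, median -0.79, adjusted p = 0.0184; 0.588 estimated), with Hba-a2 at 90.2 ± 83.2 and 389.7 ± 104 CPM, and macrophage genes (4 of 20 positive, median -0.24 but 0.060 with library size alone, 2 lower over the list alone, adjusted p = 0.00662; 0.599 estimated), with the macrophage adaptor Tyrobp at 246 ± 125 and 542 ± 61.9 CPM. Fcer1g had 287 ± 129 and 619 ± 77.4 CPM. No single gene passed edgeR's test for Kif5A vs input in dorsal root: 0 of 12681, with 416 higher and 648 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.181, while DESeq2 called 178. The spread in this fit came from all 18 libraries, the IgG libraries among them. A fit of only the 2 groups compared was not made for the comparisons with input in either tissue, so the part of the shared spread in these counts is not known. Non-overlapping genes were 31.4%, against 10% by chance, and leaving out Kif5A replicate 3 gave 1 gene and leaving out replicate 3 of every group 454.

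In sciatic nerve the same lists were under-represented with Kif5A against input, with fibroblast genes beside them and fat cell genes over-represented. The median was -0.89 for ribosomal protein genes (2 of 79 positive, adjusted p = 5.5e-28; 0.264 estimated), with Rps20 at 195 ± 106 and 520.2 ± 109 CPM. It was -0.58 for respiratory chain genes (17 of 61 positive, adjusted p = 2.3e-05; 0.67 estimated), with Ndufa5 at 80.3 ± 38.1 and 219 ± 30.9 CPM. All 9 adipocyte genes were positive, with a median of 1.77 and 5 higher over the list alone (adjusted p = 3.6e-07; 0.264 estimated). Their summed level overlapped, at 76732, 47183 and 7496 CPM with Kif5A and 14566, 16618.5 and 4980 CPM in input. Kif5A replicate 3 lay below input replicates 1 and 2. Lep, the hormone leptin, had 258 ± 190 and 52.3 ± 20.7 CPM and Adrb3, an adrenergic receptor of fat, 53.9 ± 27.5 and 14.0 ± 4.72 CPM (log2 1.95, adjusted p = 0.535). Fibroblast genes (5 of 21 positive, median -0.73, 9 lower over the list alone, adjusted p = 2.3e-05; 0.264 estimated) included Col6a1 at 461 ± 85.9 and 1039 ± 270 CPM and Igfbp6 at 949 ± 228 and 2019.6 ± 245 CPM. The fibroblast genes summed to 31122, 34705 and 15618 CPM in input and 19106, 21712 and 17027 CPM with Kif5A. Relative to library size alone, input replicate 3 thus lay below every Kif5A library. Its TMM factor was 0.869, against 1.09, 1.07 and 0.978 for Kif5A replicates 1, 2 and 3, so this order does not hold with the factors applied. Erythroid genes (1 of 7 positive, median -1.44, 3 lower over the list alone, adjusted p = 0.00566; 0.347 estimated) included Hbb-bs at 249 ± 32.1 and 728 ± 23.2 CPM. Macrophage genes (2 of 20 positive, median -0.42, adjusted p = 1.1e-04; 0.347 estimated) and muscle genes (2 of 12 positive, median -0.81, adjusted p = 8.5e-04; 0.264 estimated) were lower than other genes. So were sensory neuron genes (3 of 14 positive, median -0.82, 1 lower over the list alone, adjusted p = 0.0194; 0.316 estimated). In the last, the neurotrophin receptor Ntrk2 was at 284 ± 85.6 and 149.9 ± 46.0 CPM and Stmn2, which regulates microtubules in axons, at 61.9 ± 14.1 and 107 ± 8.33 CPM. The sensory neuron genes summed to 1756, 1610 and 4182 CPM in input and 1326, 1541 and 2523 CPM with Kif5A. Replicate 3 was highest in both, and Kif5A replicate 3 lay above input replicates 1 and 2. The transcription factor Isl1 had no count with Kif5A and 0.608 ± 0.322 CPM in input, at least 10.98-fold higher there. Of 12681 genes 0 were higher and 1 lower for Kif5A vs input in sciatic nerve (324 higher and 446 lower at an unadjusted p under 0.05; DESeq2 called 51). Retnlg, a resistin-like gene of neutrophils, outside the naming rule and chosen after its values were seen, fell by 4.52 on the log2 scale (0.111 ± 0.0594 against 2.71 ± 0.871 CPM, adjusted p = 0.00828) and had 0.145 ± 0.0990 CPM with IgG. The count was 6 without input replicate 3, 0 without Kif5A replicate 1 or 2, 5 without Kif5A replicate 3, and 0, 0 and 116 without replicates 1, 2 and 3 of every group. Non-overlapping genes made up 17.4%.

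IgG against input measures what the precipitation brings down without the Kif5A antibody. In dorsal root, Prpf39, a splicing factor (chromosome 12, 65036333 to 65063386), rose 21.3-fold, from 1.85 ± 0.626 CPM in input to 39.5 ± 24.3 CPM (SD, n = 3, adjusted p = 0.0283). The zinc finger gene Zfp869 rose from 13.4 ± 3.88 to 164 ± 85.6 CPM (adjusted p = 0.0321). Slc39a13, Ano8 and Josd2 rose by 3.89, 3.72 and 3.60 on the log2 scale. Enc1 (chromosome 13, 97241105 to 97253034) fell from 17.6 ± 6.48 to 0.0830 ± 0.0863 CPM (log2 -7.57, adjusted p = 0.0110). Lcmt2 fell from 12.5 ± 4.78 to 0.223 ± 0.155 CPM (adjusted p = 0.0148) and Efhb from 38.0 ± 26.0 to 0.150 ± 0.0648 CPM (adjusted p = 0.0215). Lrrc20 and Dok4 also fell. The respiratory chain subunit Ndufb8 fell from 171 ± 36.5 to 57.1 ± 9.43 CPM (log2 -1.58, adjusted p = 0.0411), 1 of 61 such genes to pass over all genes and 28 over the list alone (median -1.24, adjusted p = 2.0e-10; 0.721 estimated). Ribosomal protein genes (median -1.10, 12 lower over the list alone, adjusted p = 5.1e-12; 0.721 estimated) were lower than other genes. So were muscle genes (median -1.63, 7 over the list alone, adjusted p = 0.00142; 0.469 estimated), with the myosin Myh4 at 0.859 ± 0.496 against 5.55 ± 3.54 CPM, and sensory neuron genes (median -0.85, 1 over the list alone, adjusted p = 0.043; 0.721 estimated), with Sncg at 1249 ± 615 against 3099 ± 517 CPM.

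The count was 71 higher and 85 lower for IgG vs input in dorsal root, with 1157 and 1300 at an unadjusted p under 0.05 and 1417 called by DESeq2. It was 8, 60 and 1339 without IgG replicates 1, 2 and 3, 5, 6 and 13 without input replicates 1, 2 and 3, and 0, 0 and 1622 without replicates 1, 2 and 3 of every group. Of all genes, 30.5% did not overlap.

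In sciatic nerve, adipocyte genes were higher with IgG than in input. Gpihbp1, which anchors lipoprotein lipase in capillaries (chromosome 15, 75596628 to 75599481), rose 37.4-fold, from 13.4 ± 3.13 CPM in input to 502 ± 146 CPM (SD, n = 3, adjusted p = 0.0160). Nnat, an imprinted membrane protein (chromosome 2, 157560078 to 157562522), rose from 6.56 ± 3.30 to 292 ± 170 CPM (adjusted p = 0.00273). The endothelial genes Egfl7 and Esam rose to 62.7 ± 7.03 and 165 ± 64.4 CPM from 12.5 ± 6.45 and 39.9 ± 13.2 CPM, 2 of 16 in their list, 3 over the list alone (median 0.53, adjusted p = 0.0415; 0.398 estimated). The summed level of these 16 genes overlapped between the groups, at 1752 ± 211 CPM with IgG and 1616 ± 175 CPM in input. Of 9 adipocyte genes 5 rose, 9 over the list alone (median 2.57, adjusted p = 6.4e-11; 0.186 estimated), Fabp4 from 1964 ± 1137 to 14349.5 ± 4229.8 CPM and Lep from 52.3 ± 20.7 to 401 ± 247 CPM. Of 8 nuclear-retained RNAs 1 rose, 3 over the list alone (median 1.96, adjusted p = 0.0153; 0.398 estimated); this was Gm26917, at 372 ± 360 against 10.7 ± 6.67 CPM. Elane, Echdc2 and Kank3 rose by 6.62, 6.50 and 5.22 on the log2 scale. Of 7 erythroid genes 4 fell, 4 over the list alone (median -2.16, adjusted p = 0.00149; 0.398 estimated), Hbb-bs from 728 ± 23.2 to 91.2 ± 19.4 CPM. Tubb3 fell from 4.59 ± 1.53 to 0.242 ± 0.381 CPM (adjusted p = 0.0268), 1 of 19 genes of the axonal cytoskeleton, also over the list alone (median -0.75, adjusted p = 0.0102; 0.398 estimated). Map4k5, Efhb, Armcx4 and Pdzd3 fell too, and Myrfl, with a single IgG count, stood at 11.8 ± 7.10 CPM in input. Ribosomal protein genes (median -0.74, adjusted p = 9.7e-06; 0.775 estimated), muscle genes (median -1.25, adjusted p = 7.1e-04; 0.186 estimated) and macrophage genes (median -0.74, 2 lower and 1 higher over the list alone, adjusted p = 0.0346; 0.756 estimated) were lower than other genes.

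The count was 174 higher and 300 lower for IgG vs input in sciatic nerve, with 1117 and 1318 at an unadjusted p under 0.05 and 1414 called by DESeq2. It was 260, 226 and 849 without IgG replicates 1, 2 and 3, 64, 53 and 197 without input replicates 1, 2 and 3, and 10, 0 and 1224 without replicates 1, 2 and 3 of every group. In this comparison 24.1% of genes did not overlap.

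**Figure D3:**
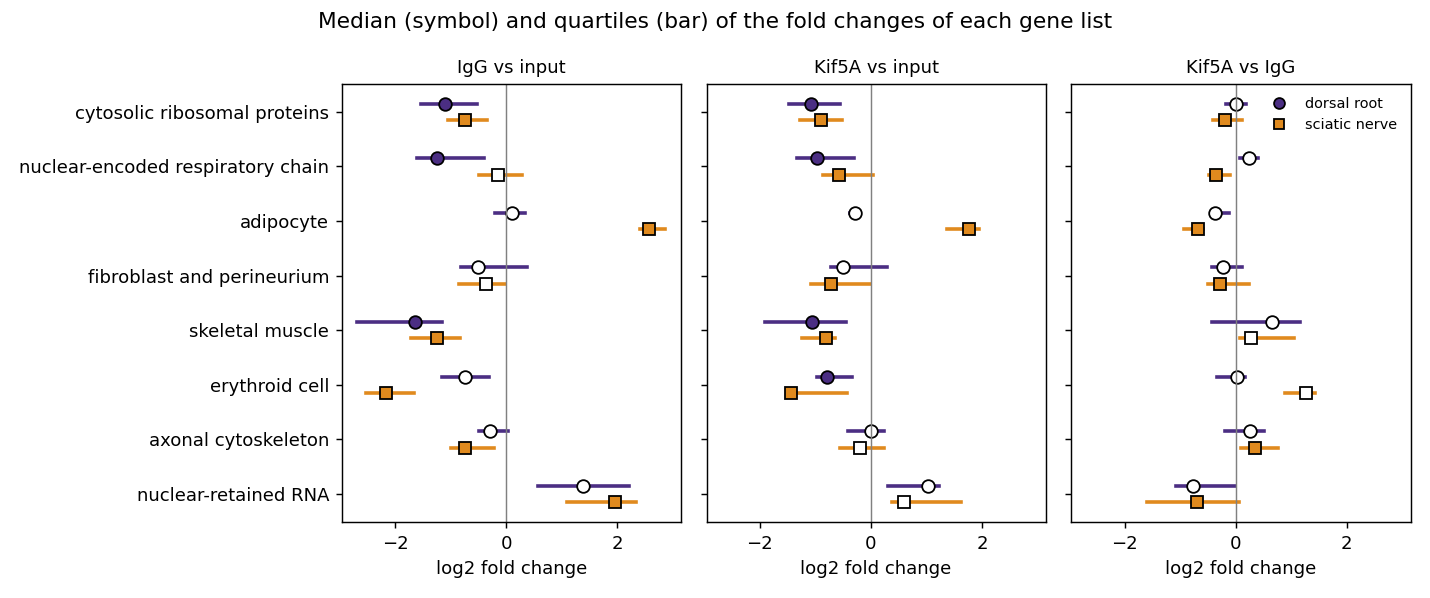
Median log2 fold change (symbol) with the quartiles (bar) of the members of 8 gene lists, in dorsal root (circles) and sciatic nerve (squares), for IgG vs input, Kif5A vs input and Kif5A vs IgG; filled symbols have a camera adjusted p under 0.05 at the preset correlation. Ribosomal protein genes have medians of -1.10 and -0.74 in IgG and -1.07 and -0.89 in Kif5A precipitates against input.

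The inputs of the 2 tissues were compared to describe the axoplasms that the precipitations start from. The sciatic nerve input held far more mRNA of adipocyte and muscle genes. The mast cell protease genes Tpsb2 (chromosome 17, 25366305 to 25369098) and Mcpt4 rose 189-fold and 132-fold, to 104 ± 21.4 and 110 ± 10.4 CPM (SD, n = 3; adjusted p = 1.3e-05 for both). All 9 adipocyte genes rose, Retn to 404 ± 131 from 3.60 ± 0.880 CPM, Car3 to 4065 ± 2056 from 60.1 ± 13.8 CPM and Lep to 52.3 ± 20.7 from 0.621 ± 0.240 CPM (median 6.09, adjusted p = 2.8e-19; 0.0606 estimated). Of 12 muscle genes 7 rose, 10 over the list alone, Ckm to 200.2 ± 38.2 from 14.4 ± 2.86 CPM (median 2.78, adjusted p = 2.3e-12; 0.0606 estimated). Pon1 and Cyp2e1 rose by 7.26 and 6.75 on the log2 scale. Of 21 fibroblast genes 10 rose (15 higher and 1 lower over the list alone), among them Gsn, which severs actin, at 4443 ± 343 against 823 ± 164 CPM (median 1.59, adjusted p = 8.2e-12; 0.155 estimated). Of 16 endothelial and mural genes 2 rose (3 higher and 1 lower over the list alone), Cspg4 to 281 ± 57.8 from 55.3 ± 7.21 CPM (median 0.58, adjusted p = 0.0176; 0.206 estimated). Ribosomal protein genes were higher than other genes (59 of 79 positive, median 0.20, adjusted p = 3.9e-04; 0.0606 estimated).

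The dorsal root input held more mRNA of glial, oligodendrocyte, presynaptic and erythroid genes. Sensory neuron genes did not pass as a list (7 of 14 positive, median -0.15, adjusted p = 0.0579), nor did macrophage and other leukocyte genes (adjusted p = 0.476). Ptgds, a prostaglandin synthase of the meninges (chromosome 2, 25466709 to 25470046), stood at 225 ± 31.9 against 0.468 ± 0.0442 CPM (log2 -8.88, adjusted p = 9.4e-06). Camp and Ngp, which encode granule proteins of neutrophils, stood at 316 ± 94.6 and 1000.3 ± 292 CPM against 0.329 ± 0.170 and 1.26 ± 0.514 CPM, and S100a8 and S100a9 had log2 ratios of -8.33 and -7.94. Of 11 satellite glia and astrocyte genes 6 fell, 7 over the list alone (median -3.57, adjusted p = 8.2e-12 and 0.0457 with an estimated correlation), such as the water channel Aqp4 at 2.30 ± 0.602 against 262 ± 33.7 CPM. Of 5 oligodendrocyte genes 3 fell, 4 over the list alone (median -4.35, adjusted p = 1.0e-07 and 0.0457 estimated), such as the myelin gene Mobp (chromosome 9, 120149707 to 120181484) at 2.76 ± 1.17 against 435 ± 188 CPM. Of 13 presynaptic genes 7 fell (9 lower and 1 higher over the list alone; median -1.48, adjusted p = 4.0e-09 and 0.0457 estimated), such as Snap25, of the vesicle fusion machinery (chromosome 2, 136713453 to 136782428), at 29.2 ± 1.52 against 621 ± 12.3 CPM. Of 19 cytoskeleton genes 4 fell, 7 over the list alone, Nefl to 17.4 ± 2.10 from 119 ± 8.51 CPM (median -0.064, adjusted p = 9.3e-04; 0.0606 estimated). Of 7 erythroid genes 4 fell, 7 over the list alone, Slc4a1 to 1.21 ± 0.686 from 64.7 ± 8.75 CPM (median -1.42, adjusted p = 4.9e-09; 0.083 estimated). Myelinating Schwann cell genes were lower than other genes, 3 over the list alone (median -0.47, adjusted p = 3.9e-04; 0.316 estimated). For input of sciatic nerve vs input of dorsal root, 285 genes were higher and 218 lower of 12215, with 1781 at an unadjusted p under 0.05 and 1064 called by DESeq2, and 21.1% did not overlap. The count was 228, 220 and 279 without dorsal root inputs 1, 2 and 3, 298, 335 and 2538 without sciatic nerve inputs 1, 2 and 3, and 132, 160 and 3517 without replicates 1, 2 and 3 of both.

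Kif5A precipitates of the 2 tissues were compared directly, to be read beside the inputs. The fat cell hormone Lep (chromosome 6, 29060220 to 29073877) stood at 258 ± 190 CPM in sciatic nerve against 0.472 ± 0.0411 CPM in dorsal root (SD, n = 3; log2 9.07, adjusted p = 4.7e-04), with 8 of 9 adipocyte genes higher (median 7.82, adjusted p = 6.1e-19 and 0.0223 estimated). Adig rose as well, and Pon1, Cfd and Tmem45b rose by 8.79, 8.60 and 8.27 on the log2 scale. Mobp was at 1.28 ± 1.11 against 1261 ± 273 CPM (log2 -9.94, adjusted p = 3.9e-04), Wnt4 and Ngp had log2 ratios of -9.06 and -8.64, and Bcan, a brain proteoglycan, had a single count against 29.1 ± 8.12 CPM. Snap25 fell by 4.08 (27.6 ± 4.46 against 467 ± 65.7 CPM, adjusted p = 2.2e-05), with 3 of 14 presynaptic genes lower, 4 over the list alone (median -1.79, adjusted p = 1.9e-11 and 0.00184 estimated). Aqp4 fell by 8.23, with 3 of 11 glial genes lower, 7 over the list alone (median -3.07, adjusted p = 5.0e-14 and 0.00222 estimated). Fibroblast genes (5 higher, 13 higher and 2 lower over the list alone, median 1.23, adjusted p = 8.6e-15 and 0.00222 estimated) and muscle genes (2 higher, 8 over the list alone, median 3.47, adjusted p = 1.2e-12 and 0.00264 estimated) were higher, as in the inputs. Oligodendrocyte (1 lower, 3 over the list alone, median -3.53, adjusted p = 7.2e-09 and 0.00222 estimated) and erythroid genes (1 lower, 5 over the list alone, median -1.79, adjusted p = 1.8e-08 and 0.038 estimated) were lower, as in the inputs. Col6a3 stood at 178 ± 70.0 against 29.5 ± 7.52 CPM, Acta1 at 258 ± 53.1 against 18.5 ± 10.8 CPM and Slc4a1 at 1.03 ± 0.709 against 65.5 ± 17.9 CPM.

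Further lists differed between the Kif5A precipitates of the tissues at the preset correlation alone. Lower in sciatic nerve were myelinating Schwann cell genes (0 called, 3 over the list alone, median -0.95, adjusted p = 6.7e-12; 0.0765 estimated) and the axonal cytoskeleton (median -0.70, adjusted p = 4.3e-05; 0.121 estimated). So were sensory neuron genes (2 called, 2 over the list alone, median -0.73, adjusted p = 1.2e-04; 0.0791 estimated), with Vsnl1, a calcium sensor, at 1.44 ± 0.736 against 68.3 ± 9.03 CPM. Motor proteins and adaptors were lower as well (median -0.14, adjusted p = 0.0443; 0.276 estimated), with Kif5a at 29.8 ± 22.2 against 133 ± 37.6 CPM (log2 -2.15, adjusted p = 0.284). Higher were endothelial genes (0 called, 1 over the list alone, median 0.99, adjusted p = 2.9e-05; 0.0513 estimated). So were ribosomal protein genes (69 of 79 positive, median 0.32, adjusted p = 5.0e-05; 0.543 estimated) and respiratory chain genes (52 of 61 positive, median 0.21, adjusted p = 2.7e-04; 0.543 estimated). For Kif5A sciatic nerve vs Kif5A dorsal root, 84 genes were higher and 40 lower, with 757 at an unadjusted p under 0.05 and 349 called by DESeq2, and 18.9% did not overlap. The count was 66, 69 and 80 without dorsal root Kif5A replicates 1, 2 and 3, 75 and 76 without sciatic nerve replicates 1 and 2, and 43 and 12 without replicates 1 and 2 of every group. Because precipitate and input share a tissue's axoplasm, these differences were not tested against those of the inputs.

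**Figure D4:**
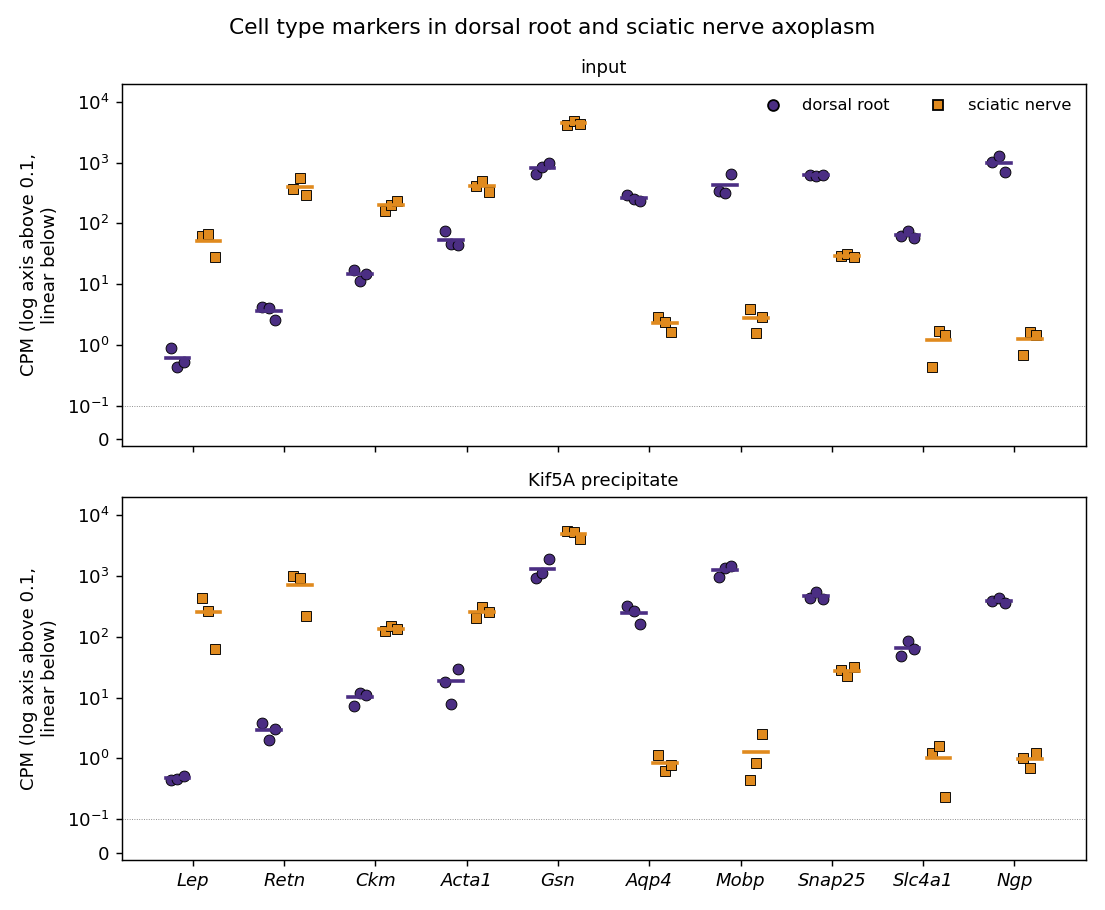
Levels of 10 cell type markers in CPM, on a log axis above 0.1 and linear below, in each library of dorsal root (circles) and sciatic nerve (squares), for input (top) and Kif5A precipitate (bottom); lines are means of 3 libraries. Lep, Retn, Ckm, Acta1 and Gsn lie higher in sciatic nerve and Aqp4, Mobp, Snap25, Slc4a1 and Ngp in dorsal root, in both panels.

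An mRNA held by the motor should be above IgG and above input, and may be held at both places. No gene passed edgeR's test over both IgG and input, 0 in dorsal root and 0 in sciatic nerve, and 0 were shared between the tissues. With DESeq2 these counts were 2, 1 and 20. In edgeR's comparisons with input, the spread was estimated with the IgG libraries included. At an unadjusted p under 0.05, 36 genes in dorsal root and 26 in sciatic nerve were higher than both. Independent lists would share 17.998 and 20.03, and unchanged groups simulated against the same Kif5A libraries shared 35.6 and 33.4 on average, and at most 46 and 47. The simulated lists differed in length from the real ones, with 282.9 and 276.7 genes on average against 543 and 416 in dorsal root and 265.65 and 282.4 against 776 and 324 in sciatic nerve, so these counts are not directly comparable. The log2 ratios over IgG and over input had a correlation of 0.0918 in dorsal root and 0.158 in sciatic nerve, against 0.497 and 0.49985 in the simulation. The simulation gave all groups the same spread for each gene, which largely sets its correlation. Real IgG libraries spread more: replicates 1 and 2 correlated at 0.737 and 0.759 with IgG, against 0.952 and 0.932 with Kif5A. The real and simulated correlations are thus not directly comparable either. At the same p, 100 genes higher with Kif5A than IgG were shared between the tissues and 37 lower genes, where independent lists would share 33.6 and 4.68. Both lists come from 1 fit with shared dispersions and hold many genes with a 0 in IgG, so independence is not the value without a change, and the planned exact test is not used here. Across all 12551 genes, which are not independent replicates, the log2 ratios of the 2 tissues had a Pearson correlation of 0.131 and a Spearman correlation of 0.124.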

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

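Mmp9 stood out because its ratio of Kif5A to IgG differed between the tissues, by 7.444 on the log2 scale, and Dab2ip for the same reason, at -11.68. The respiratory chain genes stood out for a camera adjusted p of 0.001267 for that difference, with 0.959 at an estimated correlation. The tests of read depth, independent loss, shared loss, transcript length and GC content were set after the patterns were seen, and those of Kif5A against IgG for the ribosomal protein and respiratory chain genes after the values as well.

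Both single genes had few IgG counts in a tissue, 13 for Mmp9 in sciatic nerve and, over all transcripts of its table, 37 for Dab2ip in dorsal root. The tests of missing genes concern genes at 0 in IgG libraries in general, not Mmp9, which was low but present. Read depth is excluded as the cause of the missing genes: after thinning to equal depth the percent of genes at 0 was still 6.777 times as high with IgG as with Kif5A in the tissue with the smaller ratio, and 7.22 times in the other. Loss of genes at random from each library, from few starting molecules, was asked by the genes at 0 in all 3 IgG libraries. They were 3.833 times as many as independent loss would give in a tissue and 3.51 times in the other. That expectation gives all genes of like level with Kif5A the same rate of loss in a library. Genes that differ in this rate would exceed it under random loss too, so the excess cannot exclude such loss. RNAs that come down with Kif5A and not with IgG could give the excess seen in both tissues, 3.968 times that of independent loss at like level (38 genes against 9.58), and a background poor in the same RNAs could give it as well. Dab2ip also depends on which transcripts are counted, since all transcripts of each table gave -4.69.

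Ribosomal protein mRNAs were lower than other genes in all precipitates against input at the preset correlation, and respiratory chain mRNAs in all but IgG of sciatic nerve (22 of 61 positive, median -0.15, adjusted p = 0.728). None of these list results passed with an estimated correlation. Short transcripts may be lost in general: genes matched in length had medians from -0.21 to -0.63. The list lay below them by up to 0.79 (-0.7893), above them by 0.062 in the smallest case. Genes matched in level as well had medians from -0.32 to -0.74. A set of 231 genes outside all lists, shorter than the median of either list, had medians of -1.06 and -0.77 with Kif5A against input. With IgG against input these were -1.10 and -0.51, dorsal root first, so length remains open. Whether the Kif5A antibody leaves these mRNAs behind was asked by the list medians of Kif5A against IgG. In dorsal root the lower list median was -0.001345, so neither list lay clearly lower with Kif5A there. The limit for this test was set after the values were seen, and the medians carry no interval. Summed ribosomal protein levels of the dorsal root IgG libraries ran from 6570 to 18685 CPM, so this cannot exclude a loss. The question is open for sciatic nerve too, where the lower list median was -0.3559, that of the respiratory chain genes. The median of the ribosomal protein genes there was -0.19 against IgG and already -0.74 in IgG against input, so most of that difference was present without the Kif5A antibody. Replicate 3 lay higher than replicates 1 and 2 in these lists, by a median over the groups of 0.73 and 0.46 (log2), and lower in the adipocyte genes, at -0.92.

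Replicate 3 libraries stood apart in the Kif5A and input groups, where replicates 1 and 2 had correlations of 0.952 and 0.932 with Kif5A and 0.984 and 0.987 in input, against 0.895, 0.871, 0.959 and 0.857 with replicate 3. Read depth is excluded as a likely cause, since replicate 3 had the largest total in 4 of 6 groups and the smallest in 1. Transcript length could contribute in some groups (Spearman rho -0.431 at the farthest from 0, 0.001256 at the nearest), as could GC content (0.542 and 0.07045), and both remain open.

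The libraries of the compared groups were also split in all other ways. The 10 splits of each comparison are too few for a share under 0.05. For Kif5A vs IgG in dorsal root and Kif5A vs input in dorsal root the real grouping gave 0 genes, as did all 10 splits. The real grouping alone, 1 of 10, gave its count for Kif5A vs IgG in sciatic nerve (6), Kif5A vs input in sciatic nerve (1), IgG vs input in dorsal root (156) and sciatic nerve (474), input of sciatic nerve vs input of dorsal root (503) and Kif5A sciatic nerve vs Kif5A dorsal root (124), with 0 as the highest other count. For the difference between tissues, 1 of 100 splits gave 2 genes, the real grouping, and the highest other gave 1.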

How the results depend on the processing

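Directions of named genes mostly held: of their results under alternatives, 2665 stayed the same, 133 were stronger, 195 weaker and 18 reversed. List results stayed the same in 150 cases and were weaker in 82, of which 48 were with an estimated correlation, 32 with fry and 2 with the replicate block. The likelihood ratio tests, transcript counts and all transcripts of each own table were chosen after the results were seen. Unless stated, the cause was not tested.

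Counts of genes moved with the tool, the unit and the libraries. They stayed similar in the 3 comparisons built on Kif5A against IgG when only genes above 0 in every IgG library were kept. Kif5A vs IgG in dorsal root (0) gave 158 with DESeq2, 16 with all 18 libraries, 128 with the likelihood ratio test and 1588 with that test on transcripts. Kif5A vs IgG in sciatic nerve (6) gave 411 with DESeq2, 128 with all 18 libraries, 330 with the likelihood ratio test, 1244 with that test on transcripts, 19 at an adjusted p under 0.1, 1 with the replicate block, and 0 with limma-voom, with the block within each tissue, and with only the 2 groups, also with all genes of the own table. Kif5A vs IgG difference between sciatic nerve and dorsal root (2) gave 188 with DESeq2, 144 with the likelihood ratio test, 38 with all 18 libraries, 8 at an adjusted p under 0.1, 4 with RLE, library size alone or the stricter filter, and 0 with limma-voom, either replicate block, transcripts or all transcripts of each own table. DESeq2 gave 178 for Kif5A vs input in dorsal root and 51 in sciatic nerve, 1417 for IgG vs input in dorsal root (621 with the replicate block) and 1414 for IgG vs input in sciatic nerve, 1064 for input of sciatic nerve vs input of dorsal root, 349 for Kif5A sciatic nerve vs Kif5A dorsal root, 2 and 1 for genes over both IgG and input, and 20 for the overlap between tissues.

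With a library left out, counts ran from 0 to 2 for Kif5A vs IgG in dorsal root, 0 to 29 in sciatic nerve and 0 to 24 for the difference, and from 5 to 1339 for IgG vs input in dorsal root, 53 to 849 for IgG vs input in sciatic nerve, 220 to 2538 for input of sciatic nerve vs input of dorsal root and 66 to 131 for Kif5A sciatic nerve vs Kif5A dorsal root. With a numbered replicate of every group left out as well, they ran up to 454 and 116 for Kif5A vs input in dorsal root and sciatic nerve. For IgG vs input these were 0 to 1622 in dorsal root and 0, 10 and 1224 in sciatic nerve, for the inputs 132, 160 and 3517, for the Kif5A precipitates 12, 43 and 119, and 0 to 0 for genes over both and for the overlap.

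Log2 ratios near 0 turned. Kif5b: Kif5A vs IgG in dorsal root had -0.0029 and gave 0.015 with the replicate block, 0.0025 with the block within each tissue, 0.062 with library size alone, 0.053 with limma-voom, 0.17, 0.035 and 0.090 without IgG replicate 3 and Kif5A replicates 2 and 3, and -0.14 to 0.17 over all libraries left out. Klc1: Kif5A vs IgG in dorsal root had 0.022 and gave -0.037 with RLE, -0.038 with DESeq2, -0.26 and -0.35 without IgG replicates 2 and 3, -0.011 and -0.11 without Kif5A replicates 1 and 2, and -0.35 to 1.06 over all. Kpnb1: Kif5A vs IgG in dorsal root had -0.069 and gave 0.13 and 0.019 without IgG replicate 3 and Kif5A replicate 2, and -0.22 to 0.13 over all. Klc1: Kif5A vs IgG in sciatic nerve had -0.36 and gave 0.0090 with the replicate block, 0.065 with the block within each tissue, 0.65 without IgG replicate 1, and -0.80 to 0.65 over all.

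The titles number libraries. Each library's deviations from the mean of its group, gene by gene, were correlated between libraries of different groups. These are not correlations of the levels themselves. Libraries with equal numbers had a median correlation of 0.0578 over 45 pairs, against -0.0283 for others. Deviations within a group cancel out, so the values for equal and for other numbers are not independent. For pairs of number 3 the median was 0.113 and the highest value 0.355. Of 7429 genes, 7.7%, 9.1% and 13.9% differed one way from the other numbers in all 6 groups, for numbers 1, 2 and 3. Chance gives 3.1%. Of 18 libraries, 14 had their highest mean correlation of deviations with the libraries of their own number in other groups. Per the labels both tissues came from the same animals, but which number belongs to which repeat is not stated. The closeness of equal numbers is thus a hint from the data. With the replicate block, 1 gene in place of 6 passed for Kif5A vs IgG in sciatic nerve and 0 in place of 2 for the difference between tissues. Only the 2 groups compared could not be fitted for the difference, and the alternatives for normalized values did not apply to counts. In data simulated at the real depth, with the same spread for each gene in every group, changes of 2 times were not found for Kif5A against IgG. The parts of depth and spread in this were not separated. Real IgG libraries spread more than Kif5A libraries, so the shares found in real data may differ.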

Other observations

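Nuclear-retained RNAs, long noncoding RNAs such as Meg3 and Snhg11, had a higher mean summed level in both precipitates than in input, but the libraries overlapped in part. In dorsal root their summed level was 33025 ± 4361 CPM with IgG, 25039 ± 10538 CPM with Kif5A and 8679 ± 6339 CPM in input (SD, n = 3), and in sciatic nerve 30860 ± 13523, 34312 ± 23004 and 10685 ± 7927 CPM. Oligodendrocyte genes summed to 1666 ± 231 CPM with Kif5A, 1251 ± 203 CPM with IgG and 873 ± 121 CPM in input of dorsal root. Mobp held most of this, at 1261 ± 273 CPM with Kif5A with the TMM factors applied. As a list the oligodendrocyte genes leaned the other way against IgG (1 of 5 positive, median -0.12, camera adjusted p = 0.732). Erythroid genes in sciatic nerve summed to 309 ± 52.7 CPM with IgG, 646 ± 33.7 CPM with Kif5A and 1620 ± 6.88 CPM in input. These sums were not tested. As a list, the nuclear-retained RNAs did not pass for Kif5A against input (adjusted p = 0.478 in dorsal root and 0.326 in sciatic nerve) or for IgG against input in dorsal root (0.128), and passed at the preset correlation for IgG against input in sciatic nerve (0.0153; 0.398 estimated). Its members were lower in replicate 3 than in replicates 1 and 2 by median in all 6 groups, with a median of -1.24 (log2) over the groups.

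The splits and the tools gave different pictures of Kif5A vs IgG in dorsal root. The splits with other tools were made after their counts were seen. The likelihood ratio test on transcripts gave 1588 for the real grouping and 21 to 428 for the other splits, and DESeq2 gave 158 and 4 to 143. For Kif5A vs IgG in sciatic nerve the likelihood ratio test gave 1244 against 11 to 216, and DESeq2 411 against 13 to 77. The real grouping thus gave the most genes with both tools, while groupings that mix the antibodies also gave many.

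The authors' deposited table lists 1398 transcripts of dorsal root and 1278 of sciatic nerve at a false discovery rate under 0.05 for Kif5A against IgG, and 614 and 228 against input. Of the higher named ones against IgG, 89.8% and 85.2% had a 0 in at least 1 IgG library, where 30.8% and 26.0% of all transcripts did.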
